A study of Mus musculus with 12 samples.

How the data were processed

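RNA-seq was made from 12 samples of GT1-7 cells, 4 each that received a Klf4 siRNA, a non-targeting siRNA (Scramble) or no stated transfection (Vehicle). Per the labels' protocols, the cells were kept in DMEM with 10% fetal bovine serum, RNA was extracted with Trizol and chloroform, and libraries were made with a Takara SMART-Seq low-input kit, which does not mark strand. Samples were grouped by their titles. The siRNA sequences are not given in the sources used here.

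The authors deposited a table for each of the 3 pairs of groups. Each held raw counts of reads per Ensembl gene and sample, per the file headers, and the series' design text speaks of exon counts. Per the submitters' processing notes, FastQC, STAR, STAR-Fusion, Subread and edgeR were used with the mm10 build, with no role or version stated. How the authors' counts treated reads with several matches is not given in the sources used here, so counts of close paralogs and of genes with pseudogenes were taken as uncertain. The tables also held RPKM values, which the authors made from the counts, gene lengths and an effective library size, as the ratio of deposited count to RPKM showed, and these were used only for that check. Log2 fold changes, p-values and FDR values were the authors' own statistics, per the file headers. A score per gene marked the authors' calls as up, down or neither, and the deposited values placed these at an FDR under 0.05 and an absolute log2 fold change of at least 1. The authors' tables listed genes that passed a filter on low expression whose rule is not given in the sources used here. They held 12786 genes in at least 1 table and 12443 that were tested in all 3, and a gene's count in a sample was the same in each table. Gene positions came from GENCODE M21, on the same assembly as mm10, where 12501 of 12786 gene IDs matched with their version and 12777 without it. In each table, 17 gene symbols were shared by more than 1 gene ID, and each ID was tested and counted on its own. Among list members this held for Ddit3, Aldoa and Atp5o.

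Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM scaling, the tool's default filter on low counts), with limma 3.58.1. Each comparison used only its own 8 samples, without a block, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every edgeR adjusted p is of this kind. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, counts relative to library size, scaled by TMM over all 12 samples. The 95% intervals of Klf4 are normal intervals on the log2 scale. Klf4 was also tested by a two-sided exact permutation test. Total counts per sample ranged from 25992363 to 39674984, and the biological coefficient of variation was 8% for Klf4 siRNA with Scramble, 7.3% for Scramble with Vehicle and 9% for Klf4 siRNA with Vehicle. On simulated counts with 200 changed genes per comparison, the test recovered 85.5% of changes of 0.5 on the log2 scale for Klf4 siRNA with Scramble, 81.4% for Scramble with Vehicle and 70.1% for Klf4 siRNA with Vehicle. Changes of 1 were recovered at 91.4%, 95.6% and 96.8%, and changes of 2 at 100% in each. False calls made up 7.5%, 7.9% and 6.8% of calls, more than the adjusted p of 0.05 aims at. The simulations changed far fewer genes than the 4561, 6810 and 5755 called in the data, so these rates need not hold there.

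The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, except where stated. The rule named Klf4 first, then the 10 genes with the largest rise and the 10 with the largest fall per comparison among called genes with a mean log2 CPM of at least 2 and groups that did not overlap, leaving out gene models, clones and pseudogenes. It added up to 4 called members with the smallest p from each gene list (2 members by level where none passed), and Gnrh1, Kiss1r, Esr1 and Fos, and the text names part of these, while some are not reported here. Outside this rule, the genes with the most counts, 3 gene models and the genes of further families were chosen after their values were seen.

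There were 28 gene lists: KLF family, GnRH neuron and reproductive axis, immediate-early genes, calcium channels, pumps and sensors, interferon-stimulated and innate sensing, cholesterol synthesis and uptake, unfolded protein response, integrated stress response, p53 targets, cell cycle, pluripotency factors, neurosecretion and synaptic vesicles, heat shock, serum response factor with actin and YAP targets, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, lysosome and autophagy, NRF2, FoxO and serum withdrawal, RNA interference machinery, RNA quality and nuclear RNA, and markers of astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelium, and fibroblasts and pericytes. Lists with at least 2 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Members were counted at the adjusted p over all genes and adjusted over the list alone.

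Alternatives were DESeq2 1.42.0, its size factors, library size alone, no low-count filter, a filter of 5 CPM in 4 samples, an adjusted p under 0.01, a log2 fold change of at least 1, a replicate block, each sample left out, and 1 fit of all 12 samples. After the data were seen, further ones were added: removal of a spline trend on transcript GC content and gene length per library (12772 of 12786 genes had a GC value), Klf4 siRNA samples 1 and 4 left out, the authors' FDR, and gene lists under the other scalings and with each sample left out. Relations between comparisons that share samples were set beside 20 simulations of unchanged groups, the overlap of independent lists, and 6 divisions of the shared samples. Each sample was counted as 1 replicate, and whether the samples are separate cultures or technical repeats is not given in the sources used here. Pairs of samples within a group differed by more than counting noise (mean chi-square per gene of 3.37 or more), which does not tell these apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and NumPy 2.4.6.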

Results

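RNA was sequenced from GT1-7 cells, a mouse hypothalamic line that makes gonadotropin-releasing hormone (GnRH). The 12 samples formed 3 groups of 4. One group received an siRNA against Klf4, a zinc finger transcription factor, and another received a non-targeting siRNA (Scramble), each by lipid transfection in Opti-MEM I for 24 h. The Vehicle group was not described as transfected: it was starved of serum for 6 h and then held for 1 h in medium free of Ca2+. Nothing named the samples of a group as separate cultures, so whether the spread behind the p-values lies between cultures or is technical is not known. Total counts over listed genes ranged from 30041486 to 33481453 in the Klf4 siRNA samples, from 25992363 to 39674984 in Scramble and from 28451562 to 35560442 in Vehicle. The first principal component held 53.3% of the variance and set Vehicle apart from both siRNA groups. The second held 25% and set Klf4 siRNA apart from Scramble. The gene with the most counts, without regard to gene length, was Lars2 in each Klf4 siRNA sample, Tuba1a in each Scramble sample and Hspa5 in each Vehicle sample. Lars2 was high in every group, at 4330 ± 563 CPM in Klf4 siRNA, 2880 ± 315 in Scramble and 3440 ± 198 in Vehicle (SD, n = 4). Whether its reads come from its own mRNA was not tested. Transcripts of the mitochondrial genome took 0.28% ± 0.02 of the counts in Klf4 siRNA, 0.26% ± 0.01 in Scramble and 0.27% ± 0.05 in Vehicle (SD, n = 4). Fold changes are given as the first group over the second, with a standard error (SE) on the log2 scale and 4 samples per group.

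The targeted gene, Klf4 (mm10 chromosome 4, 55527143 to 55532466, minus strand), was read at a low level. The Klf4 siRNA samples 1 to 4 held 44, 30, 61 and 45 counts of Klf4, the Scramble samples 187, 152, 93 and 121, and the Vehicle samples 166, 138, 131 and 158. Its level was 1.38 ± 0.359 CPM with the Klf4 siRNA, 4.01 ± 0.609 in Scramble and 4.78 ± 0.555 in Vehicle (SD, n = 4). Every Klf4 siRNA sample lay below every other sample. With the siRNA, Klf4 stood at 34.6% of its Scramble level (95% interval 26.6 to 45), a log2 fold change of -1.53 (SE 0.19, edgeR adjusted p = 5.8e-05). Against Vehicle it stood at 29.3% (95% interval 22.6 to 37.8), a log2 fold change of -1.77 (SE 0.19, edgeR adjusted p = 8.6e-06). Scramble stood at 84.4% of Vehicle, with a 95% interval of 69.8 to 102, and did not pass the threshold (log2 fold change -0.24, SE 0.14, edgeR adjusted p = 0.157). Two-sided exact permutation tests of Klf4 gave p = 0.0286 for both comparisons of the Klf4 siRNA, the smallest p that 70 divisions of 8 samples can give. The same exact permutation test gave p = 0.171 for Scramble against Vehicle.

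**Figure D1:**
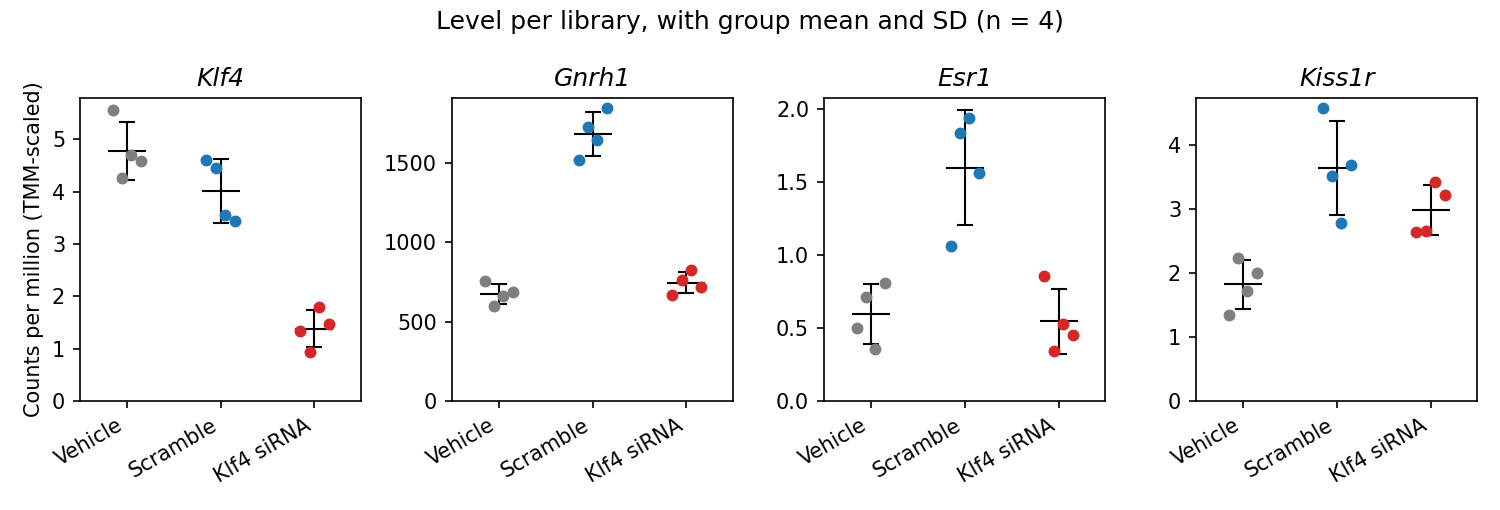
CPM of Klf4, Gnrh1, Esr1 and Kiss1r (vertical axes from 0) in each of the 4 samples of Vehicle, Scramble and Klf4 siRNA; points are samples, bars the group mean and SD. The 4 Klf4 siRNA samples sit between 0.928 and 1.8 CPM for Klf4, below all Scramble and Vehicle samples, and the 4 Scramble samples sit between 1520 and 1850 CPM for Gnrh1, above all others.

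The comparison of Klf4 siRNA with Scramble set 2 transfected groups against each other. With 1 group per siRNA, it does not part the loss of Klf4 from other effects of either siRNA. Gnrh1, the gene of the hormone that defines these cells (chromosome 14, 67745181 to 67749439, plus strand), fell from 1690 ± 139 to 745 ± 66.1 CPM (SD, n = 4). Its log2 fold change was -1.17 (SE 0.07, edgeR adjusted p = 7.2e-08). Vehicle lay at 676 ± 63.6 CPM for Gnrh1, so Scramble was the group that stood apart. Esr1, the oestrogen receptor alpha gene (chromosome 10, 4611593 to 5005614, plus strand), fell from 1.6 ± 0.396 to 0.545 ± 0.221 CPM, at 11 to 63 counts per sample in these groups (log2 fold change -1.52, SE 0.30, edgeR adjusted p = 0.00165). In Vehicle, Esr1 lay at 0.596 ± 0.203 CPM, so Scramble stood apart here too. Kiss1r, the kisspeptin receptor gene (chromosome 10, 79916971 to 79922273, plus strand), did not pass, at -0.29 (SE 0.17, edgeR adjusted p = 0.186). Large rises included Robo3, an axon guidance receptor (5.89-fold, SE 0.11), the interferon-induced Oas2 (5.88-fold, SE 0.23) and the secreted phosphoprotein gene Spp1 (5.59-fold, SE 0.12). Gpnmb, a glycoprotein of lysosomes and melanosomes, rose 4.91-fold (SE 0.07). Large falls included Kif26b, a kinesin family member (log2 fold change -2.44, SE 0.22), and Cilp, an extracellular matrix gene (-2.23, SE 0.09). The neurotrophin receptor gene Ntrk3 (-1.65, SE 0.07), the Notch target Hey1 (-1.64, SE 0.08) and Postn, which encodes periostin (-1.60, SE 0.10), fell as well. Oas2 has close paralogs, and reads shared with them left its level uncertain.

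Interferon-stimulated and innate sensing genes rose almost throughout with the Klf4 siRNA over Scramble. Of 47 measured, 44 rose, 0 fell and 3 did not pass (46 and 0 adjusted over the list alone). The transcription factor gene Irf7 rose 3.04-fold (SE 0.09) and Rtp4 4.05-fold (SE 0.14). The interferon list passed camera (adjusted p = 1.7e-43), with adjusted p = 0.0499 with an estimated correlation. Of 23 p53 target genes, 16 rose, 2 fell and 5 did not pass (17 and 2 adjusted over the list alone). They included the cyclin gene Ccng1 (2.94-fold, SE 0.05), the p53 ubiquitin ligase gene Mdm2 (2.05-fold, SE 0.06) and the cyclin-dependent kinase inhibitor gene Cdkn1a (1.88-fold, SE 0.04). The p53 list passed camera (adjusted p = 6.4e-19, and adjusted p = 0.0161 with an estimated correlation). Of 28 lysosome and autophagy genes, 22 rose, 1 fell and 5 did not pass (23 and 1 adjusted over the list alone). The cathepsin genes Ctsa (1.81-fold, SE 0.04) and Ctsb (1.79-fold, SE 0.04) were among them, and the list passed camera (adjusted p = 5.3e-27, and adjusted p = 0.0262 with an estimated correlation). GnRH neuron and reproductive axis genes fell more often than they rose: of 20 measured, 10 fell, 1 rose and 9 did not pass (12 and 1 adjusted over the list alone). Besides Gnrh1, the homeobox genes Dlx5 (log2 fold change -0.55, SE 0.04) and Six6 (-0.47, SE 0.05) fell. The GnRH list passed camera (adjusted p = 1.4e-05, and adjusted p = 0.0499 with an estimated correlation).

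Further lists passed camera between Klf4 siRNA and Scramble with its preset correlation and lost the call with an estimated one. Of 28 immediate-early genes, 14 rose, 3 fell and 11 did not pass (16 and 3 adjusted over the list alone). Myc rose 2.35-fold (SE 0.08), Atf3 1.98-fold (SE 0.08) and Fos 1.56-fold (SE 0.09). The immediate-early list had a camera adjusted p = 2.6e-06, but adjusted p = 0.109 with an estimated correlation. Of 78 cytosolic ribosomal protein genes, 73 rose, 0 fell and 5 did not pass (76 and 0 adjusted over the list alone). Rps2 rose 1.45-fold (SE 0.05), and these genes have many near-identical pseudogenes, so their counts were uncertain. The ribosomal list had a camera adjusted p = 2.7e-17, but adjusted p = 0.33 with an estimated correlation. Of 31 integrated stress response genes, targets of ATF4, 16 rose and 1 fell (18 and 1 adjusted over the list alone), with the longer of both gene IDs of Ddit3 at 0.94 (SE 0.06). Camera gave adjusted p = 1.2e-06 for them, but adjusted p = 0.17 with an estimated correlation. Of 31 cholesterol synthesis and uptake genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), with Sqle at -0.48 (SE 0.05). Their camera adjusted p = 1.1e-04 became adjusted p = 0.163 with an estimated correlation. Of 29 neurosecretion and synaptic vesicle genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone). The secretory granule gene Chgb (-1.49, SE 0.16) and Rab27b (-1.12, SE 0.07) fell, and the list's camera adjusted p = 0.025 became adjusted p = 0.163 with an estimated correlation. Without Scramble 3 or without Scramble 4, 5 of these genes fell.

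NRF2 oxidative stress genes went up with the Klf4 siRNA over Scramble, with 11 rises and 1 fall of 19 (camera adjusted p = 3.0e-04, adjusted p = 0.259 with an estimated correlation). Glycolysis and hypoxia genes had 14 rises and 3 falls of 30 (camera adjusted p = 0.0406, adjusted p = 0.409 with an estimated correlation). Serum response factor, actin and YAP targets went down, with 9 falls and 2 rises of 23 (camera adjusted p = 0.0142, adjusted p = 0.163 with an estimated correlation). So did unfolded protein response genes, with 9 falls and 2 rises of 25 (camera adjusted p = 0.0286, adjusted p = 0.17 with an estimated correlation). Cell cycle genes had 17 falls and 5 rises of 47 (camera adjusted p = 0.0286, adjusted p = 0.532 with an estimated correlation). Adjusted over the list alone, these lists gave 11 rises and 1 fall, 14 and 3, 2 and 10, 2 and 9, and 6 and 20, in that order. Without Scramble 4 the unfolded protein response and cell cycle calls ended (camera adjusted p = 0.0582 for both), as did glycolysis (camera adjusted p = 0.0542). The cell cycle call also ended without Klf4 siRNA 3 (camera adjusted p = 0.0573), and the glycolysis call without Klf4 siRNA 1 or 2 (camera adjusted p = 0.107 and 0.0556). Without Klf4 siRNA 2 the glycolysis rises were 9. NRF2 rises were 7 without Scramble 2, Scramble 3 or Klf4 siRNA 2, and with the GC and length trend removed 9 NRF2 genes rose and 4 fell.

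Of 49 calcium channel, pump and sensor genes, 16 fell and 5 rose with the Klf4 siRNA over Scramble (17 and 5 adjusted over the list alone). Camera called them (adjusted p = 0.0286, but adjusted p = 0.259 with an estimated correlation), and the call ended once a trend on GC content and length was removed (adjusted p = 0.182). The median log2 fold change of the calcium genes went from -0.13 to -0.08 with that trend removed (SD over genes 0.39 in both fits), and 17 fell and 6 rose. Nuclear-encoded oxidative phosphorylation genes counted 25 rises and 0 falls of 75 (23 and 0 adjusted over the list alone; camera adjusted p = 2.0e-04, adjusted p = 0.532 with an estimated correlation). Their rises were 9 with the trend removed, where the call ended (camera adjusted p = 0.279) as the median went from 0.15 (SD over genes 0.07) to 0.04 (SD 0.09). The count was 55 without Klf4 siRNA samples 1 and 4. It was 13 without Scramble 1, 14 without Scramble 2, and 51, 11 and 15 without Klf4 siRNA 1, 2 and 3. Those 2 samples stood apart in 3 gene models that were singled out after their values were seen. One of these, Gm10800, counted 25825 and 10572 there, and 687 and 259 in Klf4 siRNA samples 2 and 3. Among lists of other cell types, fibroblast and pericyte genes fell (4 of 6; camera adjusted p = 0.0112, adjusted p = 0.122 with an estimated correlation), with Col1a1 at -1.44 (SE 0.17). Astrocyte genes rose (2 of 3; camera adjusted p = 0.025, adjusted p = 0.259 with an estimated correlation). Microglia and macrophage (2 rose and 1 fell of 3), endothelium (1 and 1 of 2) and oligodendrocyte lineage genes (0 and 0 of 4) did not pass camera. Each of the 5 lists of other cell types gave the same counts adjusted over the list alone.

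KLF family genes went both ways with the Klf4 siRNA over Scramble and did not pass camera (adjusted p = 0.464). Of 13 measured, 5 rose, 4 fell and 4 did not pass, with the same counts adjusted over the list alone. Klf6 rose 1.53-fold (SE 0.06) and Klf2 had a log2 fold change of 0.59 (SE 0.13), while Klf4 fell. Heat shock genes (7 rose and 1 fell of 15), pluripotency factors (2 and 0 of 6), FoxO and serum withdrawal genes (4 and 3 of 17), RNA interference machinery (1 and 1 of 13) and mitochondrially encoded mRNAs (3 and 0 of 11) did not pass camera. Adjusted over the list alone, these gave the same counts except 1 and 0 for RNA interference. The heat shock list (camera adjusted p = 0.0675) was called upward without Klf4 siRNA 4 (camera adjusted p = 0.036, 7 rose and 0 fell) and without Klf4 siRNA samples 1 and 4 (camera adjusted p = 0.0488, 8 rose and 0 fell), against adjusted p = 0.375 with an estimated correlation over all samples. The signs of median, mean and test differed for the KLF family (0.05, -0.04, up), endothelium (0.65, 0.65, down) and mitochondrial mRNAs (-0.07, 0.00, up). Some genes, such as Myc, stood in more than 1 list. The list of RNA quality and nuclear RNA had 0 measured members and was not analysed here.

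Between Klf4 siRNA and Scramble, 4561 of 12663 tested genes differed in edgeR's quasi-likelihood test (adjusted p under 0.05), 2345 up and 2216 down. The changes were mostly small, with a median absolute log2 fold change of 0.31, and 200 genes rose and 141 fell at least 2-fold. The 4 samples of one group did not overlap those of the other for 34.7% of genes, where chance gives 2.86%. The authors' deposited table called 4331 of these tested genes at its own FDR under 0.05, of which 4205 were shared and went the same way.

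**Figure D2:**
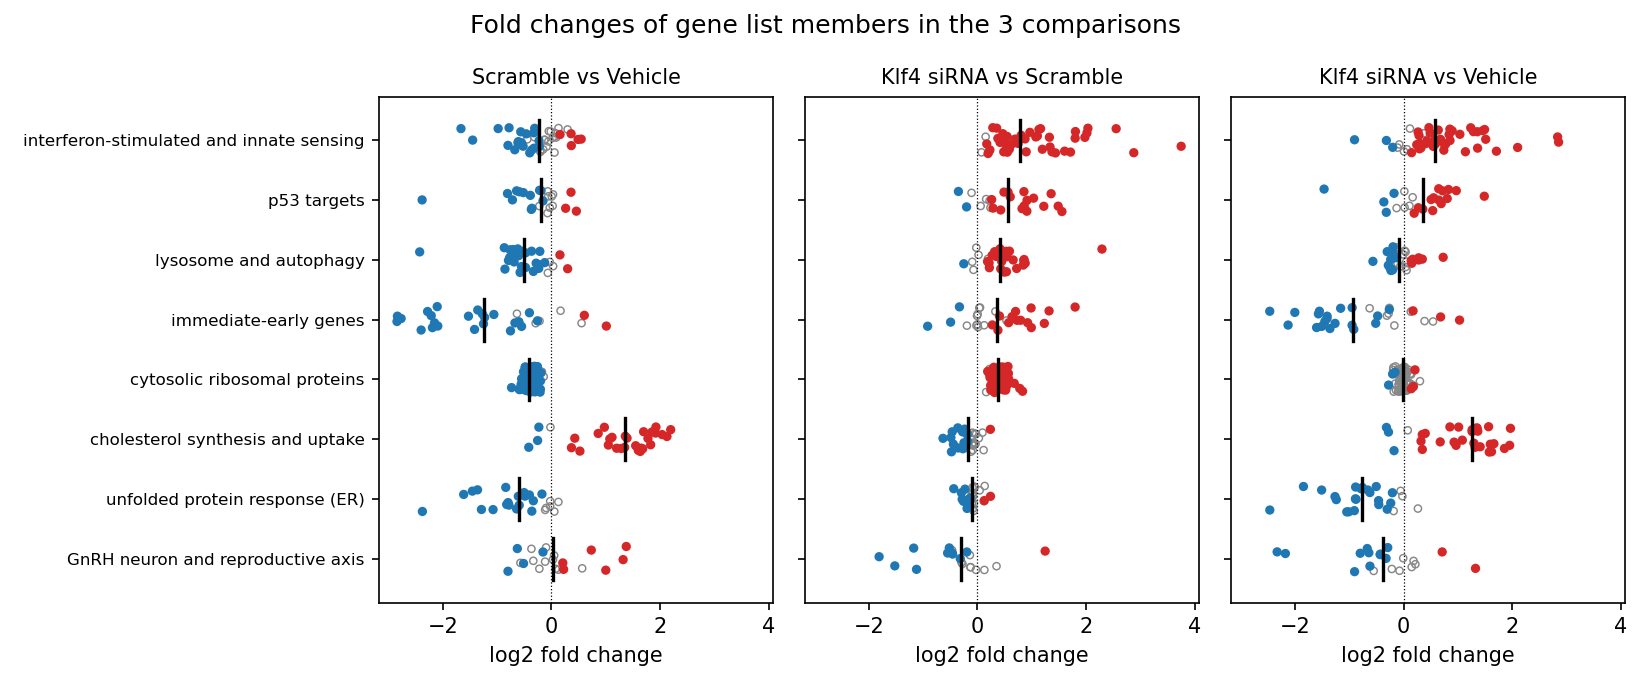
Log2 fold change of each measured member of 8 gene lists in the 3 comparisons (n = 4 samples per group); red and blue points rose and fell past the adjusted p of 0.05, open points did not pass, and black bars are medians. The interferon-stimulated list has 44 rises with Klf4 siRNA against Scramble and 5 rises with Scramble against Vehicle, and the cholesterol list has 27 rises in each comparison with Vehicle.

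The comparison of Scramble with Vehicle set cells transfected with a non-targeting siRNA against cells in medium free of Ca2+, and the groups differed in medium, serum and transfection at once. Gnrh1 was 2.5-fold higher in Scramble, at 1690 ± 139 against 676 ± 63.6 CPM (SD, n = 4; log2 fold change 1.32, SE 0.07, edgeR adjusted p = 5.3e-09). Esr1 rose by a log2 fold change of 1.38 (SE 0.28, edgeR adjusted p = 0.0011) and Kiss1r by 1.00 (SE 0.19, edgeR adjusted p = 6.2e-04), both at few counts. The smooth muscle actin gene Acta2 fell most among named genes, from 691 ± 35.4 to 37 ± 3.95 CPM (log2 fold change -4.22, SE 0.07, edgeR adjusted p = 4.3e-13). Pi16, a peptidase inhibitor gene, rose 10.5-fold (SE 0.12), the matrix gene Spon2 7.79-fold (SE 0.18), Aldoc 6.00-fold (SE 0.18) and the apelin receptor gene Aplnr 5.80-fold (SE 0.12). Cilp rose 5.27-fold (SE 0.09) and Hey1 4.77-fold (SE 0.08). Socs3, a feedback inhibitor of cytokine signalling, fell by 3.03 on the log2 scale (SE 0.22), and Gpnmb fell by 2.43 (SE 0.07).

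Cholesterol synthesis and uptake genes rose in Scramble over Vehicle: of 31 measured, 27 rose, 3 fell and 1 did not pass, with the same counts adjusted over the list alone. The synthase gene Hmgcs1 rose 3.78-fold (SE 0.04) and the epoxidase gene Sqle 3.55-fold (SE 0.05). The cholesterol list passed camera (adjusted p = 1.7e-76, and adjusted p = 3.5e-04 with an estimated correlation). Unfolded protein response genes fell: of 25 measured, 19 fell, 0 rose and 6 did not pass, with the same counts adjusted over the list alone. The chaperone gene Hspa5 went from 5000 ± 243 to 1630 ± 131 CPM (SD, n = 4), and Xbp1 (log2 fold change -1.46, SE 0.05) and Herpud1 (-1.36, SE 0.05) also fell. The unfolded protein response list passed camera (adjusted p = 1.6e-20, and adjusted p = 0.0012 with an estimated correlation). Of 23 serum response factor, actin and YAP targets, 15 fell, 3 rose and 5 did not pass, with the same counts adjusted over the list alone. Besides Acta2 they included Tagln (-2.82, SE 0.08), and the list passed camera (adjusted p = 1.8e-13, and adjusted p = 0.0409 with an estimated correlation). Of 13 KLF family genes, 9 fell, 1 rose and 3 did not pass (9 and 2 adjusted over the list alone). Klf2 was at -2.10 (SE 0.10) and Klf10 at -1.12 (SE 0.04), and the list passed camera (adjusted p = 1.1e-09, and adjusted p = 0.0127 with an estimated correlation). Of 28 lysosome and autophagy genes, 23 fell, 2 rose and 3 did not pass, with the same counts adjusted over the list alone. Ctsa was at -0.87 (SE 0.04), and the list passed camera (adjusted p = 1.4e-15, and adjusted p = 0.0251 with an estimated correlation).

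Other lists passed camera between Scramble and Vehicle with the preset correlation and lost the call with an estimated one. Of 30 immediate-early genes, 23 fell, 2 rose and 5 did not pass (24 and 3 adjusted over the list alone; camera adjusted p = 8.3e-17, but adjusted p = 0.0708 with an estimated correlation). Egr1 had a log2 fold change of -2.84 (SE 0.19), Myc -2.84 (SE 0.09) and Fos -2.77 (SE 0.22). Within Vehicle, Egr1 (459 ± 166 CPM) and Fos (101 ± 41.6 CPM) spread widely (SD, n = 4). Of 30 integrated stress response genes, 24 fell and 2 rose, with the same counts adjusted over the list alone. Ppp1r15a was at -2.11 (SE 0.05) and the longer gene ID of Ddit3 at -1.09 (SE 0.05), and the list had a camera adjusted p = 8.3e-10, but adjusted p = 0.0708 with an estimated correlation. Of 47 cell cycle genes, 37 rose and 3 fell (37 and 4 adjusted over the list alone), and Top2a rose 1.58-fold (SE 0.04). The cell cycle list had a camera adjusted p = 1.2e-09, but adjusted p = 0.112 with an estimated correlation. Of 78 cytosolic ribosomal protein genes, 74 fell and 0 rose (76 and 0 adjusted over the list alone), with Rps2 at -0.59 (SE 0.05). Their camera adjusted p = 1.4e-09 became adjusted p = 0.602 with an estimated correlation.

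NRF2 genes had 15 falls and 2 rises of 19 in Scramble over Vehicle (camera adjusted p = 7.7e-07, adjusted p = 0.112 with an estimated correlation), with Osgin1 at -1.97 (SE 0.09) and Hmox1 at -2.05 (SE 0.09). Interferon-stimulated genes had 21 falls and 5 rises of 45 (camera adjusted p = 0.00379, adjusted p = 0.503 with an estimated correlation), with Irf1 at -0.98 (SE 0.07). FoxO and serum withdrawal genes had 10 falls and 3 rises of 17 (camera adjusted p = 0.0177, adjusted p = 0.112 with an estimated correlation), with Irs2 at -1.72 (SE 0.09). Heat shock genes had 9 falls and 2 rises of 16 (camera adjusted p = 0.00948, adjusted p = 0.0726 with an estimated correlation). Adjusted over the list alone, these lists gave 15 falls and 2 rises, 21 and 5, 11 and 4, and 9 and 2. The p53 targets had 12 falls and 3 rises of 23 (camera adjusted p = 0.0463, adjusted p = 0.112 with an estimated correlation), and oxidative phosphorylation genes 32 and 1 of 75 (camera adjusted p = 0.0205, adjusted p = 0.765 with an estimated correlation). Adjusted over the list alone, they gave 12 and 3, and 28 and 1. The p53 call ended with the GC and length trend removed (camera adjusted p = 0.0549), although the median log2 fold change did not shrink, at -0.19 before and -0.21 after (SD over genes 0.56 in both fits). Its unadjusted camera p was 0.0267 before and 0.0295 after. The oxidative phosphorylation call ended as well (camera adjusted p = 0.573), with a median of -0.15 before (SD over genes 0.11) and -0.05 after (SD 0.12). The p53 call also ended without Vehicle 1, Vehicle 3, Scramble 2 or Scramble 3 (camera adjusted p = 0.0517, 0.0596, 0.0537 and 0.0552). Oxidative phosphorylation falls were 21 without Vehicle 1 or Vehicle 4, 15 without Scramble 1 and 17 without Scramble 2. They were 14, with 2 rises, under scaling by library size alone and 16, with 4 rises, with the GC and length trend removed. That call ended without Vehicle 1 or Scramble 1 (camera adjusted p = 0.11 and 0.13), and the FoxO call without Scramble 1 (camera adjusted p = 0.0528).

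In Scramble against Vehicle, GnRH axis genes (6 rose and 4 fell of 21), neurosecretion genes (11 and 9 of 30), calcium genes (19 and 8 of 50) and glycolysis genes (7 and 11 of 30) did not pass camera. The calcium list held Rcan2, a calcineurin regulator, at -1.59 (SE 0.07). Pluripotency factors (3 rose and 1 fell of 6), RNA interference machinery (3 and 2 of 13) and mitochondrially encoded mRNAs (0 and 1 of 11) did not pass either. Nor did astrocyte (1 rose and 2 fell of 3), oligodendrocyte lineage (1 and 2 of 4), microglia and macrophage (1 and 1 of 3) and fibroblast genes (1 and 3 of 6). The endothelium list held 1 measured gene, which fell, and was not tested. Adjusted over the list alone, neurosecretion genes gave 12 and 9, RNA interference machinery 3 and 1, mitochondrial mRNAs 0 and 0, microglia 1 and 2, and the others the same counts. The signs of median, mean and test differed for pluripotency factors (0.59, 0.17, down), glycolysis (-0.11, 0.01, down) and astrocyte genes (-0.37, 0.54, up).

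Between Scramble and Vehicle, 6810 of 12633 tested genes differed in edgeR's quasi-likelihood test, 3445 up and 3365 down. Scaling by library size alone gave 4248 up and 2614 down, a share of rises of 61.9% in place of 50.6%. The median absolute log2 fold change was 0.37, with 320 rises and 322 falls of at least 2-fold. The groups did not overlap for 48.3% of genes, where chance gives 2.86%. The authors' deposited table called 6906 of the tested genes at FDR under 0.05, and 6684 were shared and went the same way.

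The comparison of Klf4 siRNA with Vehicle set the knockdown against cells not described as transfected, with the same differences of medium and serum. Gnrh1 did not pass, at 745 ± 66.1 against 676 ± 63.6 CPM (SD, n = 4; log2 fold change 0.15, SE 0.07, edgeR adjusted p = 0.117). It passed in edgeR with scaling by library size alone (log2 fold change 0.20, adjusted p = 0.039), without Vehicle 1 (0.20, adjusted p = 0.0346) and without Klf4 siRNA samples 1 and 4 (0.23, adjusted p = 0.0415). Esr1 was not listed in the authors' table of this comparison. A fit of all 12 samples gave -0.15 (SE 0.35, edgeR adjusted p = 0.751), and a two-sided exact permutation test gave p = 0.714. Kiss1r rose 1.64-fold (SE 0.19, edgeR adjusted p = 0.00725). Mmp9, a gelatinase gene, rose 12.7-fold (SE 0.17), Aldoc 5.86-fold (SE 0.19), Robo3 5.80-fold (SE 0.13) and Spp1 5.58-fold (SE 0.12). Acta2 had a log2 fold change of -4.35 (SE 0.09), Tagln -3.30 (SE 0.09), the BMP antagonist gene Nog -2.50 (SE 0.13), Dner -2.45 (SE 0.05) and Serpinf1 -2.34 (SE 0.06).

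Cholesterol genes rose in Klf4 siRNA over Vehicle, with 27 rises, 3 falls and 1 that did not pass of 31 (camera adjusted p = 1.1e-56, and adjusted p = 1.8e-04 with an estimated correlation). Unfolded protein response genes fell, with 21 falls, 0 rises and 4 that did not pass of 25 (camera adjusted p = 7.3e-32, and adjusted p = 1.8e-04 with an estimated correlation). Both gave the same counts adjusted over the list alone. Hspa5 was at -1.84 (SE 0.05) and Xbp1 at -1.51 (SE 0.05). Serum response factor, actin and YAP targets had 17 falls and 2 rises of 23 (19 and 2 adjusted over the list alone; camera adjusted p = 8.4e-22, and adjusted p = 0.00538 with an estimated correlation). KLF family genes had 11 falls and 1 rise of 13, with the same counts adjusted over the list alone (camera adjusted p = 2.8e-08, and adjusted p = 0.00672 with an estimated correlation). Klf5 was at -1.19 (SE 0.08) and Klf2 at -1.51 (SE 0.10). Of 47 interferon-stimulated genes, 38 rose, 3 fell and 6 did not pass, with the same counts adjusted over the list alone. Rtp4 rose 3.27-fold (SE 0.11) and Irf7 2.44-fold (SE 0.09). Their camera adjusted p = 6.7e-14 became adjusted p = 0.164 with an estimated correlation. Of 23 p53 targets, 14 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.2e-04, but adjusted p = 0.0535 with an estimated correlation), and Ccng1 rose 2.81-fold (SE 0.08).

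Immediate-early genes fell in Klf4 siRNA over Vehicle, with 19 falls and 3 rises of 30 (20 and 4 adjusted over the list alone; camera adjusted p = 1.5e-09, but adjusted p = 0.17 with an estimated correlation). Egr1 was at -2.46 (SE 0.19) and Fos at -2.13 (SE 0.22). Cell cycle genes rose, with 26 rises and 5 falls of 47 and the same counts adjusted over the list alone (camera adjusted p = 3.5e-06, but adjusted p = 0.192 with an estimated correlation). Aurka, a mitotic kinase gene, rose 1.6-fold (SE 0.04). GnRH axis genes fell, with 11 falls and 2 rises of 20 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0146, but adjusted p = 0.138 with an estimated correlation). The oestrogen receptor gene Gper1 went from 3.69 to 0.812 CPM (log2 fold change -2.18, SE 0.21), and the neurosecretory gene Vgf rose 2.51-fold (SE 0.15). NRF2 genes (9 fell and 4 rose of 19; camera adjusted p = 0.00225, adjusted p = 0.164 with an estimated correlation) and FoxO genes (11 and 3 of 17; camera adjusted p = 0.0285, adjusted p = 0.174 with an estimated correlation) went down. So did integrated stress response genes, with 15 falls and 5 rises of 31 (camera adjusted p = 0.0287, adjusted p = 0.549 with an estimated correlation). That call ended without Vehicle 2 (camera adjusted p = 0.0651), without Klf4 siRNA 4 (0.0542) and without Klf4 siRNA samples 1 and 4 (0.051). Fibroblast genes fell (5 fell and 1 rose of 6; camera adjusted p = 0.0178, adjusted p = 0.138 with an estimated correlation). Astrocyte genes rose (2 rose and 0 fell of 3; camera adjusted p = 0.0295, adjusted p = 0.192 with an estimated correlation).

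Ribosomal protein genes (3 rose and 3 fell of 78), lysosome genes (7 and 10 of 28), oxidative phosphorylation genes (7 and 2 of 75) and calcium genes (11 and 10 of 48) did not pass camera between Klf4 siRNA and Vehicle. Neurosecretion genes (5 rose and 9 fell of 30), heat shock genes (5 and 7 of 16), glycolysis genes (11 and 8 of 30), pluripotency factors (3 and 1 of 6), RNA interference machinery (2 and 3 of 13) and mitochondrial mRNAs (0 and 1 of 11) did not pass either. Nor did oligodendrocyte lineage (1 rose and 2 fell of 4), microglia (1 and 1 of 3) and endothelium genes (1 and 1 of 2). Adjusted over the list alone, rises and falls were 0 and 0 for ribosomal proteins, 7 and 12 for lysosome genes, 1 and 0 for oxidative phosphorylation and 0 and 0 for mitochondrial mRNAs. They were 5 and 16 for the integrated stress response, 1 and 3 for the oligodendrocyte lineage, and the same for the lists whose value is not given. The signs of median, mean and test differed for pluripotency factors (0.49, 0.31, down), microglia genes (-0.13, 0.22, up) and endothelium genes (0.63, 0.63, down).

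Between Klf4 siRNA and Vehicle, 5755 of 12684 tested genes differed in edgeR's quasi-likelihood test, 3054 up and 2701 down. Scaling by library size alone gave 3758 up and 2192 down, a share of rises of 63.2% in place of 53.1%. The median absolute log2 fold change was 0.39, with 334 rises and 334 falls of at least 2-fold. The groups did not overlap for 41.2% of genes, where chance gives 2.86%. The authors' deposited table called 5682 of the tested genes at FDR under 0.05, and 5508 were shared and went the same way.

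The comparisons were set against each other over 12443 genes tested in all 3, where shared samples alone give some relation and genes are not independent replicates. Many genes moved one way from Vehicle to Scramble and the other way from Scramble to Klf4 siRNA. Lower in Scramble than Vehicle and higher with Klf4 siRNA than Scramble were 1222 genes, where independent lists would share 605, and Gpnmb, Ctsa, Myc and Fos were among them. The reverse held for 1191 genes, where independent lists would share 599, among them Gnrh1, Cilp and Hey1. Same-direction changes counted 224 up and 294 down, where independent lists would share 623 and 581. The correlation of both sets of fold changes across genes was -0.40, with a covariance of -0.061. In 20 simulations of unchanged groups sharing the Scramble samples, the correlation was -0.50 and the covariance -0.00647. The observed correlation was thus no stronger than shared samples alone give. The covariance was larger in size, but any real change of Scramble enters both comparisons with opposite signs, and the simulations held none. Its size therefore does not show a relation beyond the shared group. With separate Scramble samples in each comparison, the correlation over 6 divisions was -0.37 to -0.32. The comparisons of each siRNA group with Vehicle correlated at 0.73 across genes, with a covariance of 0.15, where simulations of unchanged groups sharing the Vehicle samples gave 0.51 and 0.00685. Divided Vehicle samples gave a correlation of 0.63 to 0.69. These comparisons shared 2017 rises and 1871 falls, where independent lists would share 813 and 701. Over the divisions of the Vehicle samples they shared 1213 to 1537 rises, where independent lists would share 465 to 650. Shared falls were 1344 to 1491 there, against 444 to 594. The Vehicle group still enters both comparisons in these divisions, and any real change of it adds to correlation, covariance and shared calls. The simulations held no such change.

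**Figure D3:**
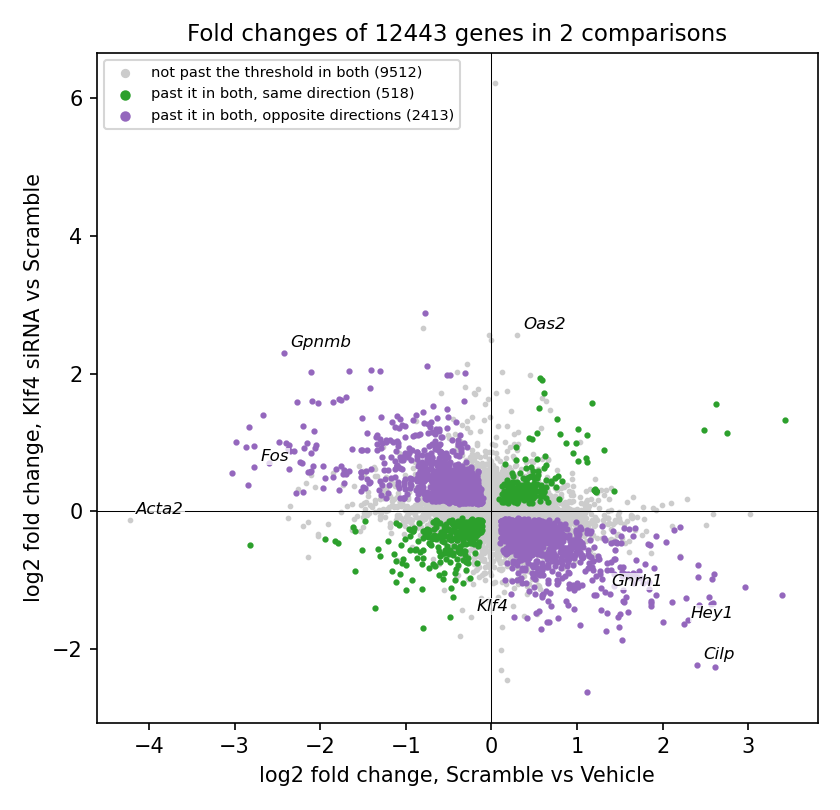
Log2 fold change of 12443 genes in Scramble over Vehicle (horizontal) and Klf4 siRNA over Scramble (vertical), n = 4 samples per group; purple genes passed in both comparisons in opposite directions, green genes in the same direction, grey genes not in both. The 2413 purple genes outnumber the 518 green ones. The Scramble samples enter both axes, which alone gave a correlation of -0.50 and a covariance of -0.00647 in simulations of unchanged groups. The genes drawn had a correlation of -0.4 and a covariance of -0.061, larger in size than the simulated one. Any real change of Scramble enters both axes with opposite signs, and the simulations held none. The larger covariance therefore does not show a relation beyond the shared group.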

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

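Chosen after the results were seen were the test of transfection itself and the fits without Klf4 siRNA samples 1 and 4 or with the GC and length trend removed. Among 198 groups of 4 samples, 10 held a sample far from the others, where chance gives about 1 in 20 groups, or 9.9. Cdkn1a stood at 327 CPM in Vehicle 1 and at 270 to 274 in the other Vehicle samples. Klf6 stood at 152 CPM in Vehicle 1 and at 128 to 130 in the others. Cilp stood at 6.68 CPM in Vehicle 2, against 5.21 to 5.35. Nog stood at 12.4 CPM in Vehicle 2, against 14.5 to 14.6. Top2a stood at 530 CPM in Vehicle 2, against 488 to 495. Fos stood at 12.8 CPM in Scramble 2, against 15.3 to 15.8. Socs3 stood at 10.2 CPM in Scramble 2, against 15.7 to 15.9. Irf7 stood at 16.7 CPM in Scramble 4, against 15.1 to 15.3. Spon2 stood at 4.86 CPM in Klf4 siRNA 1, against 3.21 to 3.25. Klf4 siRNA 3 had counts for 12778 genes and the other Klf4 siRNA samples for 12785 each.

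Interferon-stimulated and innate sensing genes rose with the Klf4 siRNA over Scramble, 44 of 47 measured. Neither GC content and length nor Klf4 siRNA samples 1 and 4 were the whole cause: 41 members rose with a trend on GC content and length removed, and 42 without these samples. Both of these groups were lipid-transfected for 24 h, so transfection as such does not part them by design. In Scramble over Vehicle 5 members rose and 21 fell. Medium and serum differed there as well, so that count does not test transfection alone. A loss of Klf4 and a response to this siRNA duplex apart from its target both remain candidate explanations, and they cannot be told apart because the design holds 1 group with a Klf4 siRNA.

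Genes that moved one way from Vehicle to Scramble moved the other way with the Klf4 siRNA, 2413 in all, of which 946 still differed between Klf4 siRNA and Vehicle and 1467, Gnrh1 among them, did not pass there, a division that follows in part from how the genes were chosen. Noise of the Scramble samples shared by the comparisons was argued against as the whole cause. With separate Scramble samples, the correlation across genes was at most -0.32 over 6 divisions. In those divisions 1293 to 1441 genes moved in opposite directions, where independent lists would share 526 to 618. The Scramble group still enters both comparisons there with opposite signs, which alone can give a negative correlation. Independent lists are thus not what groups with unrelated changes would give. With the GC and length trend removed the correlation was at most -0.31. A state particular to the Scramble cultures, such as a response to the non-targeting siRNA, may account for it as well as the loss of Klf4, and these cannot be told apart with 1 group that received a non-targeting siRNA.

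Gene models Gm10800, Gm10801 and Gm21738, chosen after their values were seen, were high in Klf4 siRNA samples 1 and 4. Gm10800 held 25825 and 10572 counts there, 687 and 259 in Klf4 siRNA samples 2 and 3, and 54 to 238 in the Scramble and Vehicle samples. Tandem repeat sequence stays open: the transcripts matched themselves at a fixed lag in at least 52.7% of bases, above the median of 29.2% for 1000 other transcripts but below their highest, 78.9%. Their best matches lay at similar lags, 225 bases in Gm10800, 231 in Gm10801 and 234 in Gm21738. The likeness of these lags goes with a shared repeat, but it was not part of the test and was seen afterwards. Genomic DNA in these samples stays open too, since the 2556 genes with the lowest levels differed between samples 1 and 4 and samples 2 and 3 by a median of 0.03 on the log2 scale, which neither calls for it nor excludes it. No biological explanation was tested, since no group of the design parts samples 1 and 4 from 2 and 3.

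Chance as the source of the gene counts was argued against in each comparison, but only at the smallest share that 35 splits can give. Of 35 splits of the 8 samples, 1, the real one, gave as many genes. Real and highest other counts were 4561 and 1 for Klf4 siRNA with Scramble, 6810 and 0 for Scramble with Vehicle, and 5755 and 0 for Klf4 siRNA with Vehicle. Every other split mixes samples of both groups, whose difference then widens the spread on each side. Its count is therefore not what unchanged samples would give. Such splits also do not tell apart cultures and technical repeats.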

How the results depend on the processing

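Added after the data were seen were the fits with the GC and length trend removed, without Klf4 siRNA samples 1 and 4, with the authors' FDR, and the gene lists under other scalings and with each sample left out. For Klf4 siRNA with Scramble, Scramble with Vehicle and Klf4 siRNA with Vehicle, in that order, the counts of changed genes stayed within 1.5 times of 4561, 6810 and 5755 except under stricter thresholds, which count fewer genes by construction. An adjusted p under 0.01 gave 2854 for the first comparison, and an absolute log2 fold change of at least 1 in addition gave 341, 642 and 668. With each sample left out, the counts were 3531 to 4634, 6085 to 6755 and 4899 to 5654. The log2 fold change of Klf4 then ranged from -1.69 to -1.38, from -0.31 to -0.16 and from -1.93 to -1.62. Lists called by camera, 18, 15 and 14, became 4, 5 and 4 with an estimated correlation, and 15 to 19, 13 to 15 and 13 to 14 with each sample left out. Some calls were lost although the estimated correlation lay below the preset 0.01. Among the gene lists these were heat shock (-0.011) and p53 targets (-0.026) between Scramble and Vehicle. The others were fibroblast genes between Klf4 siRNA and Scramble (-0.12) and between Klf4 siRNA and Vehicle (0.0036). A higher correlation thus did not account for every loss. The setting with an estimated correlation also gave weaker values where the correlation was low and the call was kept. For the unfolded protein response in the third comparison (-0.028), the camera adjusted p went from 7.3e-32 to 1.8e-04. The settings thus differ in more than the correlation, and a lost call does not by itself show correlated genes. Replicate numbers did not pair the samples consistently (correlations of -0.39 to 0.32 across genes), and a replicate block gave 3880, 6143 and 5968 genes. For replicates 1 to 4 of the third comparison the correlations were 0.32, 0.14, 0.21 and -0.05, so a weak pairing there is not excluded. With the replicate block the glycolysis list lost its call between Klf4 siRNA and Scramble (camera adjusted p = 0.0596). Fry called 25, 20 and 19 lists, which is another question than camera's, and GC and length removal left 16, 13 and 14. Over single named genes, 1575 values kept their direction and side of the threshold and 3, all of Gnrh1 between Klf4 siRNA and Vehicle, newly passed. Over gene lists, 420 stayed, 41 lost and 19 gained a call, a tally that omits the fits with samples left out. Leaving out single samples ended a list's call in 15 instances and added 1, heat shock between Klf4 siRNA and Scramble, and leaving out Klf4 siRNA samples 1 and 4 ended the integrated stress response call between Klf4 siRNA and Vehicle (camera adjusted p = 0.051). No called list and no named gene past the threshold reversed. With the GC and length trend removed, lists not called did change direction: mitochondrial mRNAs in the first and second comparison and oxidative phosphorylation in the third. Of 5642 genes called with and without that trend in the third comparison, 5641 kept their direction. Across genes, fold changes went with gene length at a Spearman correlation of -0.26, 0.14 and -0.06. Alternatives for normalised values and for tables without counts were not run, since the tables hold counts. Klf4 had 30 to 187 counts per sample, and how far depth limits its estimate was not tested.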

Other observations

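The gene families here, 30 in all, were chosen after the data were seen. With the Klf4 siRNA over Scramble, 15 of 27 collagen genes fell and 1, Col9a3, rose (log2 fold change 1.45). Col6a2 was at -1.31 (SE 0.04), Col6a1 at -0.89 (SE 0.04) and Col5a1 at -0.85 (SE 0.05), and the family had a camera adjusted p = 7.3e-09, but adjusted p = 0.0935 with an estimated correlation. Fibroblast and pericyte markers, which include collagen genes, fell in the same comparison (4 of 6; camera adjusted p = 0.0112, adjusted p = 0.122 with an estimated correlation). All 4 measured Id genes, inhibitors of helix-loop-helix factors, fell, with Id3 at -1.53 (SE 0.22) and Id2 at -1.25 (SE 0.07). The Id family had a camera adjusted p = 5.5e-05, but adjusted p = 0.119 with an estimated correlation. Of 34 potassium channel genes, 14 fell and 0 rose, with Kcnma1 at -1.54 (SE 0.06; camera adjusted p = 3.5e-04, adjusted p = 0.119 with an estimated correlation). Axon guidance genes fell: 16 of 30 semaphorin, plexin, Slit and Robo genes, with 3 rises (camera adjusted p = 3.5e-04, adjusted p = 0.168 with an estimated correlation), and 9 of 17 ephrin and Eph genes, with 1 rise (camera adjusted p = 9.1e-04, adjusted p = 0.119 with an estimated correlation). Slit2 was at -1.06 (SE 0.09) and Efnb1 at -0.61 (SE 0.05), while Robo3 was among the 3 rises, from 1.68 to 9.83 CPM. Cathepsin genes rose, 6 of 8 (camera adjusted p = 3.0e-10, adjusted p = 0.119 with an estimated correlation), as did 11 of 18 vacuolar ATPase subunits, with 1 fall (camera adjusted p = 7.0e-08, adjusted p = 0.0935 with an estimated correlation) and Atp6v0b at 0.77 (SE 0.04). The lysosome and autophagy list, which rose in the same comparison, holds genes of both families, so these are not separate results. The 3 metallothionein genes rose, with Mt1 at 1.40 (SE 0.10) and Mt2 at 1.16 (SE 0.11; camera adjusted p = 5.5e-05, adjusted p = 0.119 with an estimated correlation). Of 14 MHC class I genes, whose reads are shared among paralogs, 7 rose and 0 fell, with H2-T23 at 0.98 (SE 0.09; camera adjusted p = 0.00177, adjusted p = 0.168 with an estimated correlation).

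In Scramble over Vehicle, collagen genes went the other way, with 16 rises and 2 falls of 27 (camera adjusted p = 1.9e-04, adjusted p = 0.291 with an estimated correlation). Potassium channel genes had 19 rises and 3 falls of 34 (camera adjusted p = 2.5e-04, adjusted p = 0.207 with an estimated correlation). Neither family passed camera between Klf4 siRNA and Vehicle. Collagen genes had 8 rises and 8 falls of 26 there (camera adjusted p = 0.87), and potassium channel genes 11 and 4 of 34 (camera adjusted p = 0.492). Tubulin genes rose, 13 of 18 with 0 falls, and Tuba1a, the gene with the most counts in Scramble, rose by 1.00 on the log2 scale (SE 0.05; camera adjusted p = 8.3e-05, adjusted p = 0.356 with an estimated correlation). Sprouty, Spred and Dusp genes, feedback inhibitors of growth factor signalling, had 15 falls and 0 rises of 25, with Dusp6 at -2.15 (SE 0.09) and Spry1 at -2.02 (SE 0.14). The immediate-early list also holds Dusp genes, Dusp6 among them, so these are not fully separate results. The Sprouty, Spred and Dusp family had a camera adjusted p = 1.9e-04, but adjusted p = 0.101 with an estimated correlation. With the Klf4 siRNA over Scramble it had 10 rises and 2 falls of 25 (camera adjusted p = 0.00652, adjusted p = 0.119 with an estimated correlation).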
